A study of Mus musculus with 12 samples.

How the data were processed

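Messenger RNA was measured in 12 adult mouse hearts of the C57BL/6J background, 6 from floxed mice without Cre (the noninduced group) and 6 from floxed mice carrying MerCreMer in which, per the labels, Parkin was deleted in the adult (the Parkin KO group), 9 to 10 weeks after tamoxifen. Per the labels' protocols, the ventricular apex was frozen, RNA was extracted with Trizol, polyadenylated RNA was selected, and single-end libraries that do not keep strand were sequenced. The characteristics in the labels name the tissue as whole heart. Groups and replicate numbers were taken from the labels, and the control columns of the deposited tables, which carry a wild-type abbreviation, were matched to the noninduced group by number.

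The deposited count table holds whole reads per gene symbol, and per the submitters' processing notes Bowtie2, TopHat2 2.0.10 and HTSeq were used with mouse build mm10. The gene annotation, the counting mode and the treatment of reads with several hits are not given in the sources used here. The table has 23457 rows, of which 4873 hold no read in any library, and no row for unassigned reads. The deposited FPKM table has 23369 rows and, per the submitters' processing notes, Cufflinks 2.1 was among the tools. FPKM values of 4 genes (Abcc9, Cnot1, Myh6 and Xirp2) are listed at 0 in libraries with over 1000 counts, and these were left out of the FPKM tests as failed estimates. Among count rows, 37 carry Ensembl identifiers, all of which were matched to symbols, 2 symbols are duplicated and 27 symbols have been turned into dates. Of 684 genes on the fixed lists, 14 had no row.

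Counts were analysed in R 4.3.3 with edgeR 4.0.16, with TMM normalization, the filterByExpr low-count filter and the quasi-likelihood F test (glmQLFit and glmQLFTest), two-sided, on the group term alone. This filter left 13050 genes. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the estimate and the F statistic of the same test, and 95% confidence intervals from these. Both are therefore approximate. Expression levels are CPM values, computed from the deposited counts with TMM-scaled library sizes. Values per library were compared with exact two-sided permutation tests over the 924 splits of 12 libraries into 6 and 6, for which the smallest possible p is 0.00216. Total counts ran from 11610507 to 16884516 per library, so that 1 count was worth 0.0548 to 0.0948 CPM.

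The lists of genes were fixed before the data were examined. They cover mitophagy, mitochondrial dynamics, nuclear-encoded oxidative phosphorylation, mitochondrial DNA-encoded genes, fatty acid oxidation, glycolysis, the tricarboxylic acid cycle, mitochondrial biogenesis, the integrated stress response, the mitochondrial unfolded protein response, oxidative stress (Nrf2), p53 and DNA damage, autophagy and lysosome, ubiquitin ligases and proteasome, cardiac stress and fetal genes, circadian clock and immediate-early genes, together with markers of cardiomyocytes, atrial and conduction tissue, fibroblasts and matrix, endothelium, smooth muscle and pericytes, macrophages, lymphocytes and granulocytes, interferon and inflammation, red blood cells, adipocytes, nerve and mesothelium, and the sex chromosomes. Of 29 lists, 28 had at least 3 tested members. The sex chromosome list had 1 and was read per library. Lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01, and adjusted over the 28 lists. Camera with an estimated correlation, fry, and an exact permutation test of each library's mean score were run beside it. A list score is the mean over members of log2 CPM centred on the mean of all libraries.

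The genes named were set by a rule fixed with the lists. It takes Esr1 and A1cf, the 5 genes of smallest p in each direction where fewer than 5 pass, up to 6 list members past the threshold over all genes or over the list alone (otherwise the 2 of smallest p), and Nppa, Nppb, Myh7, Ppargc1a, Pink1, Mfn2, Bnip3, Fgf21 and Gdf15. Some genes that the rule takes are not reported here, and the counts of named genes leave them out. Positions are 1-based and come from the GENCODE annotation of GRCm38, the assembly that mm10 also names. All 85 genes looked up had 1 position there. The libraries carry no strand, so reads of genes whose exons overlap cannot be told apart. Exons of genes on the opposite strand covered over 10% of the exon bases of 12 of these genes, and exons of genes on the same strand did so for 6. Among them are Acadvl (42.9% with Dvl2), Htra2 (43.7% with Aup1 and Loxl3), Tagln (67.9%), Pln (64.7%), Nppa (61.5% with a noncoding gene), Ndufa13 (30.0% with Tssk6), Hyal1 (55.0% with Naa80 and Hyal3), Praf2 (35.9%) and Cpt1b (81.4% with a read-through model).

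The same code was tested on simulated data drawn from the real means and library sizes of the Parkin KO against noninduced comparison (13050 genes, 5 simulations, 200 changed genes in each). It recovered 2.8% of genes changed 1.25-fold, 42.8% of those changed 1.5-fold, 83.6% of those changed 2-fold and 94% of those changed 4-fold, and called 23 of 63500 tests of genes with no simulated change, a number that leaves out the oxidative phosphorylation list, which was shifted as a set, and genes below the filter. A simulated shift of 0.2 log2 in the oxidative phosphorylation list was found in 5 of 5 simulations, while 2 of 135 tests of other lists were called. Genes were drawn independently of each other, whereas the estimated correlation in the real data was 0.319 for this list and 0.531 for fatty acid oxidation. The simulations therefore cannot show how often lists of correlated genes are called without a change. The recovery rates also rest on 200 changed genes per simulation and on independent draws, so recovery in the real data may be lower.

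Alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, limma-voom with and without quality weights, other low-count filters, a replicate block, 1 surrogate variable from sva 3.50.0, robust empirical Bayes, an adjusted p threshold of 0.1, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and fits without each library in turn. Fits without noninduced libraries 1 and 3, without noninduced libraries 2 and 5, with female libraries alone, and with a sex term were chosen after seeing the data. The sex term set Parkin KO libraries 2, 5 and 6 as male and all others, noninduced library 3 included, as female. It is thus estimated within the Parkin KO group alone. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.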

Results

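Polyadenylated RNA of the ventricular apex was sequenced from 12 adult mouse hearts, 6 noninduced and 6 Parkin KO. Parkin is an E3 ubiquitin ligase that marks damaged mitochondria for removal by mitophagy, and the comparison asked how far its loss in the adult heart alters the messenger RNA profile. MerCreMer is a Cre recombinase fused to mutated ligand-binding domains of the mouse estrogen receptor, which enters the nucleus when tamoxifen binds. Per the labels only the Parkin KO group carried it, so effects of Parkin loss and of MerCreMer itself cannot be told apart. Total counts per library were 14797332 ± 2098499 (SD, n = 6) in noninduced and 15229253 ± 1205841 (SD, n = 6) in Parkin KO hearts, a difference within the spread between replicates (exact permutation p = 0.667). Spearman correlations between libraries ran from 0.967 to 0.991, and no 2 libraries of the same group agreed within sampling noise.

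Esr1, the estrogen receptor gene on which reads of the MerCreMer transgene can be counted, stood at 3173 ± 1022 CPM in Parkin KO and 285 ± 390 CPM in noninduced libraries (SD, n = 6 each). Every Parkin KO library, from 1553 to 4683 CPM, lay above every noninduced library, from 24.0 to 962 CPM (exact two-sided permutation p = 0.00216, adjusted p = 0.0346 over 16 library measures). A1cf, at the locus where the widely used cardiac MerCreMer transgene has been mapped, had 2 to 26 reads in Parkin KO libraries and 0 to 4 in noninduced ones (exact permutation p = 0.00433, adjusted p = 0.0346).

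Esr1, on chromosome 10 from 4611593 to 5005614 of GRCm38, had a log2 fold change of 3.48 ± 0.82 (SE). It did not pass the edgeR test (adjusted p = 0.417), in which the noninduced libraries varied widely. The library labelled noninduced replicate 1 held 558 CPM of Esr1 and the library labelled noninduced replicate 3 held 962 CPM, against 24.0 to 64.9 CPM in the other noninduced libraries. Without these 2 libraries, a choice made after seeing the data, the log2 fold change was 6.07 (edgeR, adjusted p = 1.48e-05). Leaving out the noninduced libraries of highest Esr1 must raise its fold change, so this call is no separate support. Label groups were kept throughout, and every direction below rests on labels that Esr1 goes against in 2 noninduced libraries.

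Xist, the noncoding RNA of the inactive X chromosome, and 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) showed that sex differed between the groups. Parkin KO libraries 2, 5 and 6 held 495 to 634 Y-linked reads and at most 5.25 CPM of Xist. Parkin KO libraries 1, 3 and 4 and all noninduced libraries but replicate 3 held at most 7 Y-linked reads and at least 84.2 CPM of Xist. The library labelled noninduced replicate 3 held both, with 178 Y-linked reads and 77.2 CPM of Xist. Male hearts were thus present in the Parkin KO group alone as whole libraries.

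**Figure D1:**
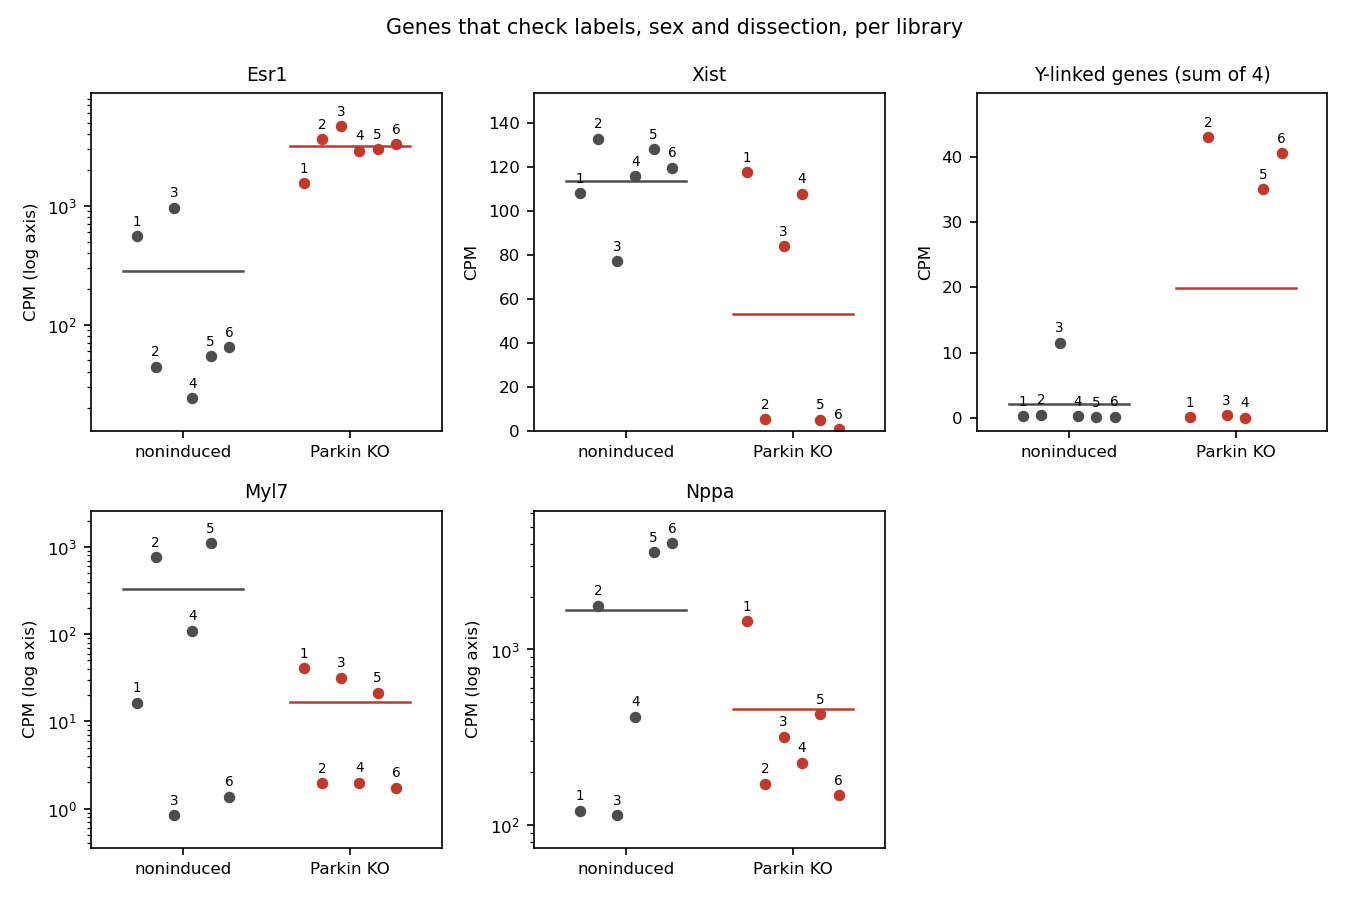
CPM in each of the 12 libraries for Esr1, Xist, the sum of 4 Y-linked genes, Myl7 and Nppa. Points carry the replicate number, horizontal lines are group means, and the axes of Esr1, Myl7 and Nppa are logarithmic. Esr1 is above 1550 CPM in every Parkin KO library, and the libraries labelled noninduced 1 and 3 lie between these and the other noninduced libraries.

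The genes with the smallest p that were higher in Parkin KO hearts were Coq7, an enzyme of coenzyme Q synthesis (log2 fold change 0.56 ± 0.122, SE), Zfp386 (0.70 ± 0.158), Hyal1, a lysosomal hyaluronidase (0.53 ± 0.124), 1810043G02Rik (0.39 ± 0.086) and Esr1. Those lower in Parkin KO hearts were Praf2 (-0.65 ± 0.118), Lyve1, a hyaluronan receptor of lymphatic endothelium and resident macrophages (-0.70 ± 0.15), the immediate-early transcription factor Egr3 (-1.74 ± 0.38), Creb3l2 (-0.64 ± 0.142) and C1qtnf6 (-0.56 ± 0.128). Coq7 stood at 47.7 ± 4.68 CPM in Parkin KO and 32.4 ± 6.64 CPM in noninduced hearts, and Praf2 at 7.58 ± 0.783 and 11.9 ± 1.96 CPM (SD, n = 6 each). None of these genes passed (edgeR, adjusted p = 0.417 for each). All 6 Parkin KO libraries lay on the same side of the noninduced mean for each of them, which a choice by smallest p favours.

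Over 13050 tested genes, 0 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.417. At an unadjusted p under 0.05 there were 1483 genes, 760 higher and 723 lower in Parkin KO, where 652 would be expected with no change. This number was 932 without noninduced replicate 2, 944 without Parkin KO replicate 6, 972 without noninduced replicate 1 and 2131 without noninduced replicate 4. It was 886 with a sex term and 628 of 13321 tested genes among female libraries. Groups did not overlap for 45 genes (0.345%), against 0.216% by chance. DESeq2 called 10 genes, with Coq7, Esr1, Idh2 and Myzap higher and Praf2, Egr3, Lyve1, Atf5, Creb3l2 and Mthfd2 lower, with a smallest adjusted p of 0.01, and limma-voom called 0. Myzap lies outside the naming rule and was named after its values were seen. Its log2 fold change was 0.31 ± 0.0791 (SE) in edgeR (adjusted p = 0.417).

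Coq7 lies on chromosome 7 from 118509659 to 118533356, Hyal1 on chromosome 9 from 107576927 to 107581710, Zfp386 on chromosome 12 from 116047724 to 116063360 and 1810043G02Rik on chromosome 10 from 77978524 to 77986905. Lyve1 lies on chromosome 7 from 110850607 to 110863239, Praf2 on chromosome X from 7728439 to 7731064, Egr3 on chromosome 14 from 70077203 to 70082614, Creb3l2 on chromosome 6 from 37327255 to 37442146 and C1qtnf6 on chromosome 15 from 78523346 to 78531416, all protein-coding in GRCm38. Hyal1 shares 55.0% of its exon bases with Naa80 and Hyal3 and Praf2 shares 35.9% with a read-through model, so their counts are uncertain.

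**Figure D2:**
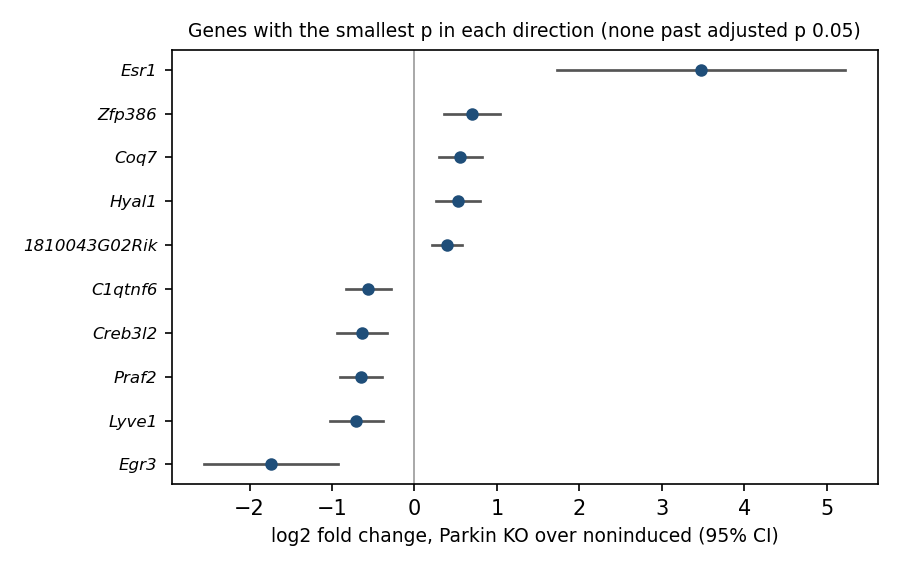
Log2 fold change of Parkin KO over noninduced hearts for the 5 genes of smallest p in each direction, from the edgeR fit. Points are estimates and lines are 95% confidence intervals, and each gene had an adjusted p of 0.417.

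The median half-width of the approximate 95% confidence interval was 0.286 log2 units per gene. For 12180 genes (93.3%) the whole interval lay within 1 log2 unit of 0, and for 9265 genes (71%) it lay within a 1.5-fold change. Among the genes tied to Parkin, Pink1, the kinase that recruits it to damaged mitochondria, had an interval of -0.209 to 0.385, Mfn2, a mitofusin it ubiquitinates, one of -0.098 to 0.262, and the mitophagy receptor Bnip3 one of -0.25 to 0.354 (edgeR, adjusted p = 0.803, 0.682 and 0.892). Ppargc1a, a coactivator of mitochondrial biogenesis, had an interval of -0.637 to 0.439 (adjusted p = 0.885).

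Genes of fatty acid oxidation, the main fuel pathway of the adult heart, were higher as a set in Parkin KO hearts by camera with the preset correlation, with 33 of 34 tested members higher and a median log2 fold change of 0.37. This call was lost with an estimated correlation (adjusted p = 0.297), and the median was 0.28 without noninduced replicate 6, the library of lowest score. Examples are Acads (0.41 ± 0.106, SE) and Acadvl (0.44 ± 0.132), acyl-CoA dehydrogenases, Hadhb (0.50 ± 0.155) of the trifunctional protein, Mlycd (0.51 ± 0.153) and Cpt1b (0.38 ± 0.116), the muscle carnitine palmitoyltransferase. In this list 0 members passed over all genes and 18 passed when adjusted over the list alone, all higher. Nuclear-encoded oxidative phosphorylation genes had 48 of 56 members higher and a median of 0.21, among them Ndufa13 (0.35 ± 0.112) and Cox4i1 (0.33 ± 0.108). The tricarboxylic acid cycle list had 18 of 20 members higher and a median of 0.20, with 2 members, Idh2 (0.38 ± 0.097) and Suclg1 (0.32 ± 0.097), past the threshold when adjusted over the list alone. The mitochondrial unfolded protein response list had 16 of 18 members higher, a median of 0.19, and 2 members past the threshold when adjusted over the list alone, the inner membrane protease Spg7 (0.44 ± 0.118) and the intermembrane protease Htra2 (0.35 ± 0.103).

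By camera with the preset correlation, adjusted p was 2.22e-13 for fatty acid oxidation, 6.04e-11 for oxidative phosphorylation, 2.67e-06 for the tricarboxylic acid cycle and 1.12e-06 for the mitochondrial unfolded protein response. With an estimated correlation the adjusted p was 0.297, 0.299, 0.345 and 0.153, and none of these 4 lists passed. The fatty acid oxidation score was 0.192 ± 0.249 in Parkin KO and -0.192 ± 0.279 in noninduced libraries (SD, n = 6 each), with an exact permutation p of 0.0303 (adjusted p = 0.106 over 28 lists). The mitochondrial unfolded protein response score was higher in all 6 Parkin KO libraries than in any noninduced library (exact permutation p = 0.00216, adjusted p = 0.0606). Among female libraries without the library labelled noninduced 1, the fatty acid oxidation median was 0.24.

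The 13 protein-coding genes of mitochondrial DNA went the other way, all 13 lower in Parkin KO hearts with a median log2 fold change of -0.57. Cytochrome b (mt-Cytb) was at -0.78 ± 0.301 (SE) and mt-Atp8 at -0.76 ± 0.264, and 0 members passed over all genes or when adjusted over the list alone. They took 10.3 ± 4.06% of counts in noninduced and 7.11 ± 1.65% in Parkin KO libraries (SD, n = 6 each, exact permutation p = 0.115), with 15.2% and 15.4% in noninduced libraries 1 and 2. By camera the adjusted p was 1.12e-06 with the preset correlation and 0.345 with an estimated correlation. Without noninduced libraries 1 and 3 the median was -0.37.

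Mitochondrial dynamics genes had 12 of 15 members higher and a median of 0.12, with the fission GTPase Dnm1l at 0.27 ± 0.096 (SE) and Rhot2, a mitochondrial transport GTPase, at 0.17 ± 0.074. Ubiquitin ligase and proteasome genes had 26 of 34 members higher and a median of 0.09, with Psmd4 at 0.28 ± 0.086. In both lists 0 members passed over all genes or when adjusted over the list alone. Camera gave adjusted p = 0.015 and 0.00236 with the preset correlation, and adjusted p = 0.345 for both with an estimated correlation. The mitochondrial dynamics call was lost without Parkin KO replicate 2 (median 0.10, adjusted p = 0.101), noninduced replicate 5 (0.08, adjusted p = 0.0587) or noninduced replicate 6 (0.06, adjusted p = 0.155), among female libraries (0.14, adjusted p = 0.0829) and among these without noninduced replicate 1 (0.09, adjusted p = 0.0511), and with a sex term (adjusted p = 0.209). The ubiquitin and proteasome median was 0.06 without noninduced replicate 1 and 0.05 without noninduced replicate 2.

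Immediate-early genes, which cells induce within minutes of a stimulus, were lower in Parkin KO hearts by camera with the preset correlation, with all 26 members lower and a median log2 fold change of -0.47. This call was lost with an estimated correlation (adjusted p = 0.282). Egr3, Fosb (-2.25, 95% confidence interval -3.58 to -0.911), Nr4a3 (-2.71 ± 0.843, SE), Ctgf (-0.92 ± 0.27) and Egr1 (-0.69 ± 0.222) passed when adjusted over the list alone, and 0 passed over all genes. Nr4a3 was highest in noninduced libraries 1, 2 and 3, at 78.6, 79.7 and 39.1 CPM, and among Parkin KO libraries in replicate 1, at 22.6 CPM. The same 3 noninduced libraries had the highest shares of counts from mitochondrial DNA (15.2, 15.4 and 10.0%) and the lowest TMM factors of their group (0.884, 0.909 and 0.973). Genes of the integrated stress response, which the transcription factor ATF4 drives, were lower in 18 of 24 members with a median of -0.24. Atf5 (-0.91 ± 0.209), the folate enzyme Mthfd2 (-1.02 ± 0.241) and the amino acid transporter Slc7a5 (-0.61 ± 0.172) passed when adjusted over the list alone.

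Camera gave adjusted p = 3.05e-11 for the immediate-early list and 0.000715 for the integrated stress response with the preset correlation, and with an estimated correlation the integrated stress response did not pass either (adjusted p = 0.121). Among female libraries without the library labelled noninduced 1, the medians were -0.15 and -0.13 and neither list passed (adjusted p = 0.0587 and 0.0651).

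**Figure D3:**
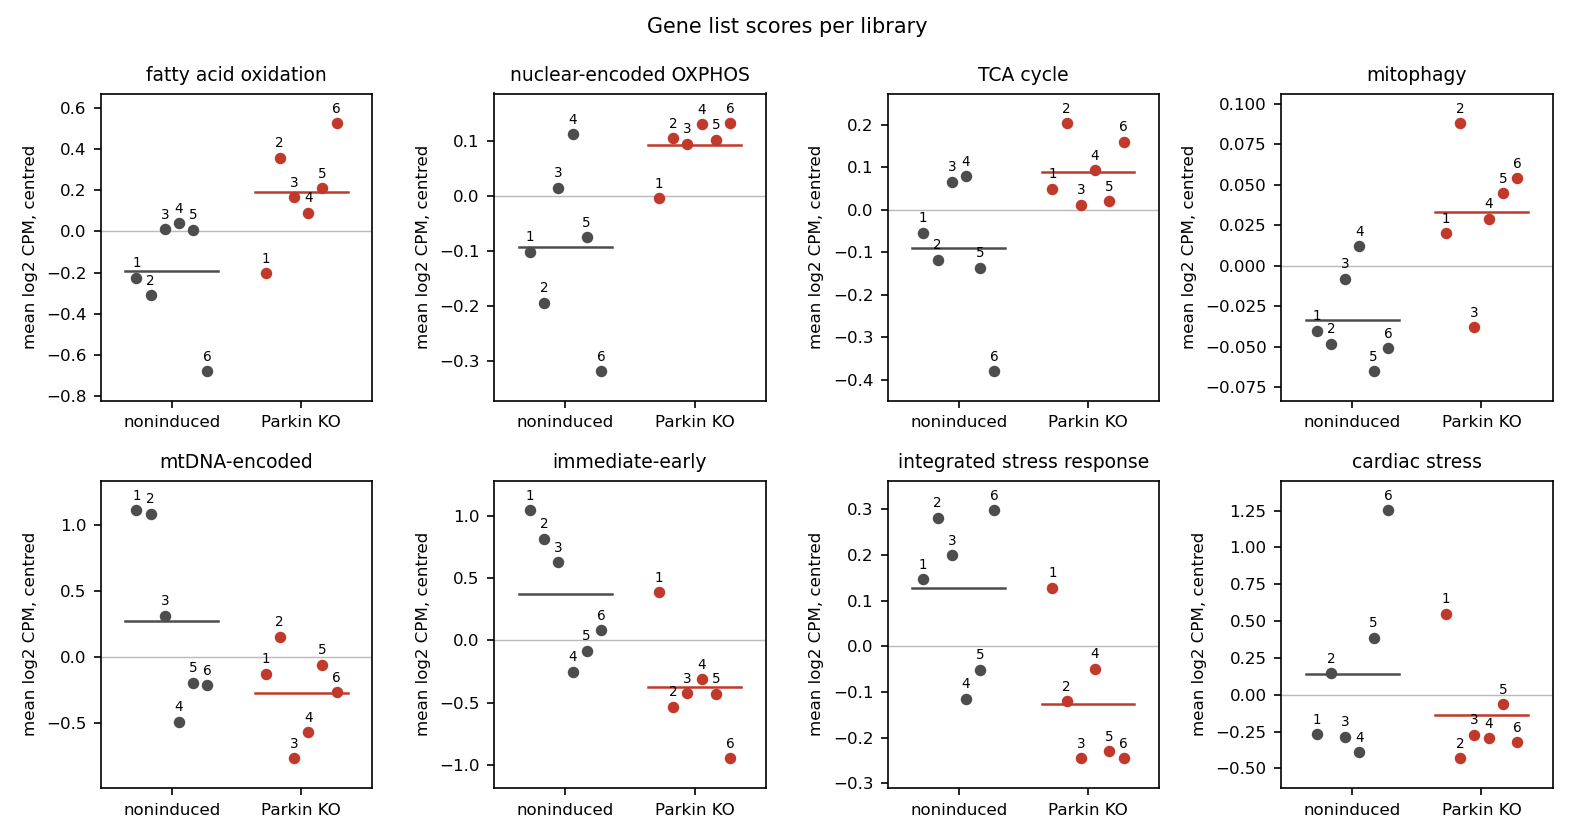
Score of 8 gene lists in each of the 12 libraries, as the mean over members of log2 CPM centred on the mean of all libraries. Points carry the replicate number and horizontal lines are group means. The lowest fatty acid oxidation score and the highest cardiac stress score are those of noninduced replicate 6, and immediate-early scores are highest in noninduced replicates 1, 2 and 3.

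Cardiac stress and fetal genes were lower in 22 of 24 members, with a median log2 fold change of -0.30. Ctgf, a matrix-associated growth factor, was at -0.92 ± 0.27 (SE) and the lectin Lgals3 at -1.56 ± 0.484, and 0 members passed over all genes or when adjusted over the list alone. The natriuretic peptide Nppa stood at 1680 ± 1779 CPM in noninduced and 457 ± 498 CPM in Parkin KO hearts, and Nppb at 234 ± 189 and 161 ± 116 CPM (SD, n = 6 each, edgeR adjusted p = 0.432 and 0.633). Fetal myosin Myh7 (log2 fold change 0.49 ± 0.77) and Gdf15 (-1.17 ± 0.782) did not pass (edgeR, adjusted p = 0.804 and 0.541), and Fgf21, at 0 to 10 reads per library, was too low to test. On leaving out 1 library, log2 fold changes ran from 0.18 without Parkin KO replicate 6 to 2.16 without noninduced replicate 6 for Myh7, and from -2.35 without Parkin KO replicate 1 to 0.18 without noninduced replicate 6 for Gdf15. Camera gave adjusted p = 0.00231 with the preset correlation and adjusted p = 0.409 with an estimated correlation. The call was lost without noninduced replicate 6 (median -0.18, adjusted p = 0.49) and with a sex term (median -0.19, adjusted p = 0.141).

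Atrial and conduction genes were lower in Parkin KO libraries in 15 of 17 members. The atrial light chains Myl7 (log2 fold change -4.32 ± 1.42, SE) and Myl4 (-4.18 ± 1.28), sarcolipin (Sln, -4.48 ± 1.3), Bmp10 (-5.39 ± 1.5) and Dkk3 (-2.88 ± 0.801) passed when adjusted over the list alone and did not pass over all genes. Myl7 was at 1107, 760 and 109 CPM in noninduced libraries 5, 2 and 4, at 16.4 CPM or below in the other noninduced libraries, and between 1.73 and 40.7 CPM in Parkin KO libraries. The list median was -0.47 (camera, adjusted p = 0.00409 with the preset correlation and adjusted p = 0.409 with an estimated correlation). The call was lost without noninduced replicate 5 (median -0.30, adjusted p = 0.191), without noninduced libraries 2 and 5 (median -0.11, adjusted p = 0.871) and with a sex term (adjusted p = 0.0851). The median was -0.81 without noninduced replicate 6 (adjusted p = 6.51e-06), -0.76 with a replicate block (adjusted p = 5.91e-06) and -0.99 without noninduced libraries 1 and 3 (adjusted p = 7.77e-06).

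Of the other cell types, fibroblast and matrix genes were lower in 28 of 32 members (median -0.22), with Thbs1 at -1.30 ± 0.346 (SE) and Sparc at -0.47 ± 0.147. Macrophage genes were lower in 18 of 23 members (median -0.14), with Cd68 at -0.43 ± 0.131. Smooth muscle and pericyte genes were lower in 13 of 18 members (median -0.14), with Ndufa4l2 at -0.52 ± 0.155 and Tagln at -0.67 ± 0.229. In these 3 lists 0 members passed over all genes or when adjusted over the list alone. Camera gave adjusted p = 9.33e-05, 0.00168 and 0.00486 with the preset correlation, and adjusted p = 0.409, 0.409 and 0.121 with an estimated correlation.

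Without noninduced replicate 6 the fibroblast call was lost (median -0.11, adjusted p = 0.126), as was the macrophage call (-0.11, adjusted p = 0.0974), and the smooth muscle call was lost among female libraries (-0.09, adjusted p = 0.0829), among these without noninduced replicate 1 (-0.10, adjusted p = 0.0946) and with a sex term (-0.08, adjusted p = 0.119). The fibroblast median was -0.12 without Parkin KO replicate 2, and the macrophage median ran from -0.31 without Parkin KO replicate 6 to -0.08 without Parkin KO replicate 3, with -0.22, -0.21 and -0.23 without Parkin KO replicate 5, noninduced replicate 1 and noninduced replicate 3. Both medians were wider, at -0.36 and -0.22 with a surrogate variable (adjusted p = 9.02e-13 and 1.95e-05), -0.42 and -0.27 without noninduced libraries 1 and 3 (2.22e-10 and 4.15e-07) and -0.42 and -0.38 among female libraries without noninduced replicate 1 (3e-10 and 2.13e-13). The macrophage median was -0.31 among female libraries and -0.28 with a sex term.

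The remaining 14 lists did not pass by camera with the preset correlation. Mitophagy genes had 18 of 25 members higher and a median log2 fold change of 0.08 (adjusted p = 0.0886), with the import receptor Tomm20 at 0.17 ± 0.074 (SE) and the deubiquitinase Usp30 at 0.15 ± 0.08. Cardiomyocyte genes had a median of 0.09 (adjusted p = 0.119), with the light chain Myl3 at 0.33 ± 0.12 and phospholamban (Pln) at 0.30 ± 0.111. Glycolysis had a median of 0.13 (adjusted p = 0.103), with Ldhb at 0.31 ± 0.102 and Pfkm at 0.29 ± 0.109, and mitochondrial biogenesis one of 0.07 (adjusted p = 0.147), with Pprc1 at -0.33 ± 0.142 and Polg at 0.17 ± 0.086. Inflammation and interferon genes had a median of -0.09 (adjusted p = 0.0886), lymphocyte and granulocyte genes -0.14 (adjusted p = 0.159), nerve and mesothelial genes -0.04 (adjusted p = 0.147), circadian clock genes -0.06 (adjusted p = 0.268), red blood cell genes -0.12 (adjusted p = 0.462) and adipocyte genes 0.13 (adjusted p = 0.305). Autophagy and lysosome genes had a median of 0.02 (adjusted p = 0.653) and Nrf2 oxidative stress genes one of -0.008 (adjusted p = 0.997). The p53 list had a median of 0.03 and a mean of -0.03 (adjusted p = 0.657), and the endothelial list a median of -0.01 and a mean of 0.02 (adjusted p = 0.923), so that median and test differed in sign in both. On leaving out 1 library, medians ran from 0.02 (without noninduced 6) to 0.13 (without noninduced 4) for cardiomyocyte genes, from 0.05 (without noninduced 2) to 0.09 (without noninduced 3) for mitophagy and from 0.08 (without noninduced 5) to 0.14 (without noninduced 3) for glycolysis. They ran from 0.04 (without Parkin KO 2) to 0.10 (without Parkin KO 5) for mitochondrial biogenesis, from 0.01 (without noninduced 6) to 0.14 (without noninduced 1) for adipocytes, from -0.23 (without noninduced 3) to -0.03 (without Parkin KO 1) for lymphocytes and granulocytes and from -0.11 (without noninduced 5) to -0.03 (without Parkin KO 5) for the circadian clock.

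Under some alternatives 7 of these 14 lists passed by camera with the preset correlation, and 0 passed with an estimated correlation or by fry. The p-values below are not corrected for the 23 alternatives run per list, so single passes may be chance. Glycolysis and cardiomyocyte genes passed with a surrogate variable (adjusted p = 0.0324 and 0.00743), without Parkin KO replicate 6 (0.0441 and 0.0419), without noninduced replicate 1 (0.0341 and 0.0184), without noninduced replicate 3 (0.0424 and 0.0404), without both of these (0.00728 and 0.00187) and among female libraries (0.00769 and 0.023) with or without noninduced replicate 1. Glycolysis also passed with a sex term (0.014). Inflammation and interferon genes passed with a surrogate variable (0.0167), without Parkin KO replicate 6 (0.00153), without noninduced replicate 3 (0.00853), without noninduced libraries 1 and 3 (0.00384) and among female libraries (0.0256) with or without noninduced replicate 1. Mitophagy genes passed with a surrogate variable (0.0177) and without noninduced libraries 1 and 3 (0.0366). Nerve and mesothelial genes passed with a replicate block (0.0106), without noninduced replicate 3 (0.0298) and without noninduced libraries 1 and 3 (0.00537). Red blood cell genes passed without Parkin KO replicate 4 (0.0497) and lymphocyte and granulocyte genes without noninduced libraries 2 and 5 (0.036).

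Among members of these lists, Cd4 (-0.76 ± 0.24, SE) passed when adjusted over the 6 tested lymphocyte and granulocyte genes alone. Fabp4 (0.33 ± 0.117) and Scd1 (-0.56 ± 0.196) passed when adjusted over the 8 tested adipocyte genes alone. These 3 genes did not pass over all genes, and Fabp4 did not pass over the endothelial list (edgeR, adjusted p = 0.298). Cd4 had 14 to 48 reads per library. The cell cycle inhibitor Cdkn1a stood at 18.8 ± 5.59 CPM in Parkin KO and 35.5 ± 14.5 CPM in noninduced hearts (SD, n = 6 each, edgeR adjusted p = 0.417), and the plasma peroxidase Gpx3 at 349 ± 78.5 and 630 ± 325 CPM (adjusted p = 0.417).

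In all, 14 of the 28 lists passed by camera with the preset correlation, 6 higher and 8 lower in Parkin KO, whereas 0 passed with an estimated correlation, 2 by fry (mitochondrial unfolded protein response, and smooth muscle and pericytes) and 0 by the exact permutation test of scores. Without noninduced libraries 1 and 3 there were 19 lists, which included all 14.

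Libraries of one group resembled each other little more than those of the other group. The mean distance (1 minus Spearman correlation) between groups was 1.1 times that within groups (exact one-sided permutation p = 0.0628). The ratio was 1.16 without noninduced replicate 3, 1.2 without noninduced replicate 4 and 1.2 without noninduced replicate 6 (exact permutation p = 0.0238, 0.0152 and 0.0173), past the threshold in each, and 0.931 among female libraries.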

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

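The tests on Esr1, on the atrial genes, and on noninduced replicate 6 and sex for fatty acid oxidation were chosen only after the results were seen; the test with the cardiac stress score was not. Of 230 groups of 6 libraries checked by Dixon's ratio for a library far from the others, 22 had one, against about 12 at a nominal 1 in 20. That rate assumes normally distributed values. CPM were not transformed here and the groups share libraries, so 22 against 12 does not show an excess.

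Esr1 reads stood out in the libraries labelled noninduced 1 and 3. For replicate 3, 178 Y-linked reads were counted, against 2 to 5 in the other noninduced libraries. Their share was 28.7% of the male mean, with an Esr1 share of 28.1%, so RNA or reads of a male Parkin KO library may have been mixed in. Xist lay 39.1% of the way from the mean of noninduced 2, 4, 5 and 6 (124 CPM) to the male mean. It adds little, since Parkin KO 3, with 7 Y-linked reads, was also low in Xist (84.2 CPM). A1cf had 0 reads in replicate 3, against 8, 10 and 12 in Parkin KO 2, 5 and 6, which lends a mixture no support, though these reads are few. A single heart with a wrong label is argued against, since Xist was still at 62.1% of the mean of noninduced 2, 4, 5 and 6 beside the Y-linked reads. For replicate 1, Esr1 was at 17% of the female Parkin KO mean while Y-linked reads were at 0.672% of the male mean, which argues against a male source, and a swap with a Parkin KO library is argued against by the lowest Esr1 there, 1550 CPM. A female Parkin KO source and a heart that carries the transgene at a low level cannot be told apart for replicate 1, because both would give this Esr1 share.

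Atrial genes, lower in Parkin KO, followed noninduced libraries 2, 4 and 5, and Bmp10 at 124.4 CPM in noninduced 5 and at 2.552 CPM in Parkin KO 5 lay far from its group. The ratio of Myl7 to Myl4 stayed between 1.24 and 1.47 (coefficient of variation 6.3%) in the 7 libraries above 10 CPM of Myl7, and the list had an adjusted p of 0.871 (camera) and a median of -0.11 without noninduced 2 and 5, but leaving out the libraries of highest atrial reads must weaken the call and co-regulated genes would keep 1 ratio as well, so atrial tissue in some noninduced samples and a difference in expression cannot be told apart. Nppa, Myl7, Myl4 and Sln reached 3607, 1107, 795 and 130 CPM in noninduced 5, and of the 20 atrial genes 1 is on another list and 13 are above 1 CPM in the library of lowest Myl7. Lower expression in every Parkin KO heart stays open, since the 2 noninduced libraries at or below the highest Parkin KO library in all 5 leading genes are replicates 1 and 3, whose labels Esr1 goes against, although noninduced 6, whose label Esr1 supports, was so in 4 of the 5 (Dkk3 at 28.3 CPM was above) and speaks against it.

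Fatty acid oxidation genes, higher in Parkin KO with a median log2 fold change of 0.37, were also weighed against the state of single hearts. The median was 0.278 without noninduced replicate 6, 0.286 among female libraries and 0.297 with each library's cardiac stress score in the fit. The list passed by camera with the preset correlation of 0.01 in all 3 (adjusted p = 4.97e-08, 6.48e-07 and 4.69e-09). Its estimated correlation was 0.531, so these passes cannot exclude any of the 3 as the cause. The medians show only that a positive shift remained in each fit. Over the 12 libraries the 2 scores were related (Pearson r = -0.77, permutation p = 0.00359, adjusted p = 0.0251; Spearman rho = -0.734, permutation p = 0.00826, adjusted p = 0.0289, over 7 relations), but r was -0.435 (permutation p = 0.207) without noninduced 6 and Parkin KO 1, the 2 libraries farthest out, whose removal narrows the range and weakens r by itself. Within groups r was -0.797 in noninduced and -0.818 in Parkin KO hearts (exact permutation p = 0.0569 and 0.0528, adjusted p = 0.0817 for each). Spearman rho was -0.829 and -0.714 (exact permutation p = 0.0583 and 0.136, adjusted p = 0.0817 and 0.159). The within-group relations thus did not pass, and each group holds 1 of the 2 libraries farthest out. An effect of Parkin loss or of MerCreMer, which cannot be told apart here, stays open. So does chance, since a change in the same direction did not pass by camera with an estimated correlation (adjusted p = 0.297).

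Noninduced replicate 6 lay far from its group in Myh7 (6462 CPM, others 316 to 680), Nppb (614 CPM, others 104 to 200), Gdf15 (28 CPM, others 1.33 to 3.99) and Cpt1b (10.25 CPM, others at least 14.2). Parkin KO replicate 1 lay far from its group in Nppa (1450 CPM, others 147 to 427), Gdf15 (12.16 CPM, others at most 1.58), Nr4a3 (22.64 CPM, others at most 3.72), Ctgf (190 CPM), Thbs1 (18.5 CPM), Mlycd (70.81 CPM), Pink1 (598.5 CPM), the cardiac stress score (0.549) and the oxidative phosphorylation score (-0.004, others at least 0.095). Parkin KO replicate 2 lay apart in Lyve1 (20.8 CPM), Icam1 (10.73 CPM) and its TMM factor (0.9607). Single departures were Bnip3 in Parkin KO 3 (32.24 CPM, others at least 48.4), Fabp4 in noninduced 2 (174 CPM, others at least 246), A1cf in noninduced 2 (0.379 CPM, 4 reads) and the adipocyte score in noninduced 4 (-0.129).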

How the results depend on the processing

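Fits without noninduced libraries 1 and 3 or 2 and 5, among female libraries and with a sex term, and the test of scores per library, were chosen only after the data were seen. The count of 0 genes held in 27 of 30 alternatives, and the direction held for 71 of 79 named genes and for all 14 called lists in every alternative run. DESeq2 called 10 genes, Esr1 among them (log2 fold change 3.46, adjusted p = 0.0346). Without noninduced 1 and 3, 1 gene was called, Esr1 (6.07). The same held among female libraries without noninduced 1 (1 gene, 6.00, adjusted p = 0.00204). Leaving out noninduced libraries high in Esr1 must raise its fold change, so these 2 calls are no separate support. Over alternatives the log2 fold change of Esr1 ran from 2.98 to 6.07 (adjusted p 1.48e-05 to 0.844). Called lists numbered 0 by camera with an estimated correlation, 2 by fry and 0 by scores per library. The distance ratio was 1.18 without noninduced 1 and 3 (exact permutation p = 0.0238), 0.931 among female libraries and 0.945 without noninduced 1 as well, with 1.02 to 1.2 on leaving out 1 library, past the threshold without noninduced 3, 4 or 6.

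Same-numbered libraries deviated together little (correlations -0.099, 0.166, -0.086, 0.097, 0.054 and 0.141), and 1 of the 6 Parkin KO libraries correlated best with its own number. These values give no sign that numbers pair the samples, but they cannot exclude it. With a replicate block 0 genes passed (edgeR, smallest adjusted p = 0.12), 1700 had an unadjusted p under 0.05, and 15 lists were called.

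Directions turned as follows, in values that did not pass, and the cause was not tested. The log2 fold change of Ppargc1a was 0.0776 with a surrogate variable, 0.0399 without noninduced 2 and 5, and 0.025 and 0.0239 in the female fits with and without noninduced 1. Bnip3 was at -0.0107 with a surrogate variable, -0.0356 without noninduced 1 and 3, -0.0787 and -0.168 in these female fits and -0.0786 with a sex term. In the same female fits Slc4a1 was at 0.23 and 0.14 (0.25 with a sex term), Myh7 at -0.17 and -0.45, and, in the second, Per1 at 0.12 and the circadian list at 0.0629. List medians without noninduced 2 and 5 were -0.014 for autophagy, -0.0306 for endothelium and 0.25 for nerve and mesothelium, and the endothelial median was 0.00625 with a sex term. The Nrf2 list, at -0.00796 (-0.00796 by fry, -0.00848 with the replicate block), changed the direction of its test. Medians this near 0 also changed sign where the test did not turn, at -0.0308 for p53 and 0.00766 for endothelium with a surrogate variable and -0.0017 for autophagy with RLE size factors, and over all alternatives they ran from -0.0559 to 0.0723 for p53, -0.0306 to 0.0363 for endothelium, -0.024 to 0.0479 for autophagy and -0.0795 to 0.0281 for Nrf2. On leaving out 1 library, log2 fold changes ran from -0.962 to 0.0222 for Nppb, -0.299 to 0.0576 for Ppargc1a, -0.0233 to 0.145 for Pink1, -0.021 to 0.141 for Bnip3 and -2.35 to 0.18 for Gdf15, and, with no turn, from 0.038 to 0.0994 for Mfn2, 0.103 to 0.196 for Polg, 0.182 to 2.16 for Myh7, -0.678 to -0.241 for Per1 and -0.874 to -0.0542 for Slc4a1, and medians from -0.0582 to 0.0281 for Nrf2, -0.0394 to 0.0723 for p53, -0.0306 to 0.00653 for endothelium, -0.305 to 0.0235 for red blood cells, -0.317 to 0.134 for nerve and mesothelium, -0.024 to 0.0479 for autophagy and -0.2065 to 0.000675 for inflammation. At this depth and n, a 1.5-fold change was recovered in 42.8% of simulated genes. Those simulations held 200 changed genes each, drawn independently, so recovery in the real data may be lower.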

Other observations

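The choice of the genes described next was made after their values were seen, while the counts over other splits of the samples were planned. Within the fatty acid oxidation list the widest shifts were in Angptl4 (log2 fold change 1.5 ± 0.531, SE), Acot1 (1.13 ± 0.399), Ucp3 (1.02 ± 0.352) and the pyruvate dehydrogenase kinase Pdk4 (0.97 ± 0.345). Each passed when adjusted over the list alone (edgeR, adjusted p = 0.0319) and not over all genes (adjusted p = 0.417). In the same list Ppara was at -0.12 ± 0.129 (adjusted p = 0.707), and the lipases Lpl and Pnpla2 were at 0.06 ± 0.109 and 0.04 ± 0.17 (adjusted p = 0.838 and 0.928).

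In the integrated stress response list Atf4 was at -0.34 ± 0.133 (SE) and Phgdh at -0.44 ± 0.171 (edgeR, adjusted p = 0.424 for each), while Ddit3 was at 0.05 ± 0.099 (adjusted p = 0.859) and Asns at -0.29 ± 0.392 (adjusted p = 0.762). In smooth muscle, Cnn1 was at -1.06 ± 0.384 and Acta2 at -0.50 ± 0.255, with adjusted p = 0.0741 and 0.256 over the list alone.

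Chance could not be excluded for the count of genes at an unadjusted p under 0.05 or for the count of lists. Among 100 splits of the 12 libraries into 6 and 6, the real one included, all 100 gave at least the 0 genes past adjusted p 0.05 of the real split, as any split must, so this count says nothing about chance, and the highest of the others gave 25. For unadjusted p under 0.05, 12 of the 100 splits gave at least the 1483 genes of the real split, with 2962 in the highest of the others. For lists past the threshold, 13 of the 100 splits gave at least 14, and the highest of the others gave 20. The split with 25 genes, picked here as the highest, set Parkin KO 1, 5 and 6 with noninduced 4, 5 and 6 against the rest. A structure of the samples other than the labelled groups is thus possible and was not tested. These 6 libraries are the 6 with the highest surrogate variable, which is estimated from the same variation and so adds no separate support, and with this variable in the fit 0 genes passed, 1637 had an unadjusted p under 0.05, and 18 lists passed, which included all 14.

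Low levels of Esr1 were present in noninduced libraries 2, 4, 5 and 6, at 0.756% to 2.05% of the Parkin KO mean. Xist was at 5.25, 5.03 and 0.7 CPM in the male Parkin KO libraries 2, 5 and 6.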
